A study of Danio rerio with 12 samples.

How the data were processed

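Messenger RNA was measured in cells sorted from adult zebrafish brains. Per the labels, Tg(her4.1:EGFP) fish aged 6 months received a cerebroventricular injection of amyloid-β42 peptide (AB42) or of the control peptide, which the labels call CPP. Brains were taken 48 hours after injection, dissociated enzymatically and sorted by flow cytometry into GFP-positive cells, in which the her4.1 reporter marks radial glia, and GFP-negative cells. The 2 injections and 2 fractions give 4 groups of 3 libraries, and all 12 libraries were used. Whether the replicates of a group came from separate fish is not given in the sources used here, so the replicates may be technical, and every p-value below measures only the spread between libraries. The labels' protocols describe poly-dT primed cDNA with template switching, PCR amplification, shearing and single-end sequencing of 75 bases on a HiSeq2000. Amplified reads without molecular identifiers are not independent molecules, so the detection floors used here cover counting error only.

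The deposited table holds read counts per Ensembl gene, which the authors made with BWA 0.7.12 and featureCounts per the submitters' processing notes. Those notes name the builds GRCz10 and danRer10; the strand setting, the annotation release, the version of featureCounts and any filters are not given in the sources used here. All values are whole numbers, and no normalisation had been applied to them. The table lists 31953 genes, of which 26121 matched a symbol in the name table supplied with the files. Of those, 4140 share their symbol with another gene, and the Ensembl identifier is printed wherever that could matter. Total counts ran from 9262838 to 15584769 per library. Coordinates are those of the deposited table: the chromosome, the first exon start and the last exon end. The 37 mitochondrially encoded genes had 0 counts in every library, so the list of mitochondrially encoded genes was not tested.

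Differential expression was computed from the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups (20237 genes), libraries were scaled by TMM, and a single model with 4 group means was fitted by quasi-likelihood with 8 residual degrees of freedom before moderation. The Benjamini-Hochberg adjustment was applied within each comparison and genes with an adjusted p under 0.05 were counted as past the threshold. Fold changes carry the prior count of 0.125 that edgeR adds. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM after TMM scaling, given as mean ± SD with n = 3 libraries. A gene with 0 counts in a whole group is given as a lower bound from a floor of 3 counts per library. The 6 comparisons are AB42 against CPP in each fraction, GFP-positive against GFP-negative cells after each injection, the difference of the 2 AB42 effects and their average.

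Gene lists were tested with camera in limma 3.58.1 on voom values with the preset correlation of 0.01 between genes, adjusted over the 28 lists of each comparison that had at least 5 genes tested. The number of members past the threshold is given as well, both with the adjustment over all genes and adjusted over the list alone. The lists cover radial glia and neural stem cells, cell cycle and DNA replication, neurogenic progenitors and newborn neurons, mature neurons, synapse, oligodendrocyte lineage, microglia and macrophages, neutrophils and lymphocytes, endothelium and mural cells, erythrocytes, motile cilia and ependyma, inflammatory cytokines and NF-kB, IL4-STAT6 signalling, Notch signalling, interferon response and antigen presentation, ER stress and unfolded protein response, heat shock proteins and chaperones, immediate early genes and dissociation stress, apoptosis and growth arrest, cholesterol synthesis, amyloid precursor processing and lipid transport, reactive glia and brain regeneration, BMP, TGF-beta and Id genes, Wnt signalling, neurotrophin signalling, extracellular matrix and meninges, nuclear-encoded oxidative phosphorylation, and cytosolic ribosomal proteins. Of 1030 listed symbols 698 matched regardless of case, 249 matched after removal of a paralog letter, 20 matched through an older symbol and 63 matched nothing.

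The comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. In each of the 4 direct comparisons the rule names the 8 largest rises and the 8 largest falls among genes past the threshold, with no overlap between the libraries of the 2 groups, at least 5 CPM in the higher group and a symbol that is not a clone name. It adds the 3 members with the smallest p of each list that passed, and 16 genes fixed by name. Some genes that the rule selects are not reported here. For the difference of the 2 effects it names 4 genes in each direction. The text gives a selection of these genes.

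Simulated counts were drawn independently for each gene from its mean over all 12 libraries, its estimated spread and the library sizes. Known changes were placed in the AB42 GFP-positive libraries, and the single changed genes had a mean of at least 1 CPM. The gene test was then run for AB42 against CPP in GFP-positive cells (19586 genes tested). It recovered 5 of 50 genes changed 1.25-fold, 25 of 50 changed 1.5-fold, 44 of 50 changed 2-fold and 50 of 50 changed 4-fold, and 2.67% of its calls were false. camera called the 1 list that had been raised 1.5-fold and none (0) of 28 random lists. Because genes were drawn independently, this does not show how camera treats lists of correlated genes. The alternatives were size factors by relative log expression (RLE), library totals only, no filter, at least 10 counts in 6 libraries, DESeq2 1.42.0, limma voom with sample weights, a fit of only the 6 libraries compared, an adjusted p under 0.1, an added 2-fold minimum, a replicate block, and leaving out each library in turn. For lists they were an estimated correlation, fry and cameraPR. After seeing the data, a fit without malat1 and the 4 hsp70 genes and a chaperone list without those 4 genes were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

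Libraries of a group were similar but not copies. Spearman correlations ran from 0.988 to 0.992, and the chi-square per degree of freedom from 2.10 to 4.84 over the 12 pairs, above the value of 1 that reads drawn again from a single library would give. The common biological coefficient of variation in edgeR was 0.0776.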

Results

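Gene expression was profiled in 12 sequencing libraries from adult zebrafish brains, 3 in each of 4 groups. The groups combine the injection, CPP control peptide or AB42, with the sorted fraction, GFP-negative or GFP-positive cells of the her4.1 reporter line. Total counts per library ran from 9262838 to 15584769 in CPP GFP-negative cells and from 12996462 to 14843229 in CPP GFP-positive cells. They ran from 12777104 to 15027301 in AB42 GFP-negative cells and from 10419435 to 13750673 in AB42 GFP-positive cells. Between 23083 and 25194 genes had at least 1 count in a library. The non-coding RNA malat1 held a large share of all counts, at 17.2 ± 0.159% in CPP GFP-negative and 20.2 ± 0.801% in CPP GFP-positive cells, and at 15.3 ± 0.215% and 15.4 ± 0.615% after AB42 (SD, n = 3). Together 4 hsp70 genes, which encode stress-inducible chaperones, held 3.54 ± 0.0131% and 3.93 ± 0.0984% after CPP and 5.79 ± 0.0546% and 5.16 ± 0.177% after AB42. The first principal component held 83% of the variance and separated the 2 fractions, and the second held 5.79% and separated the injections within each fraction.

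**Figure D1:**
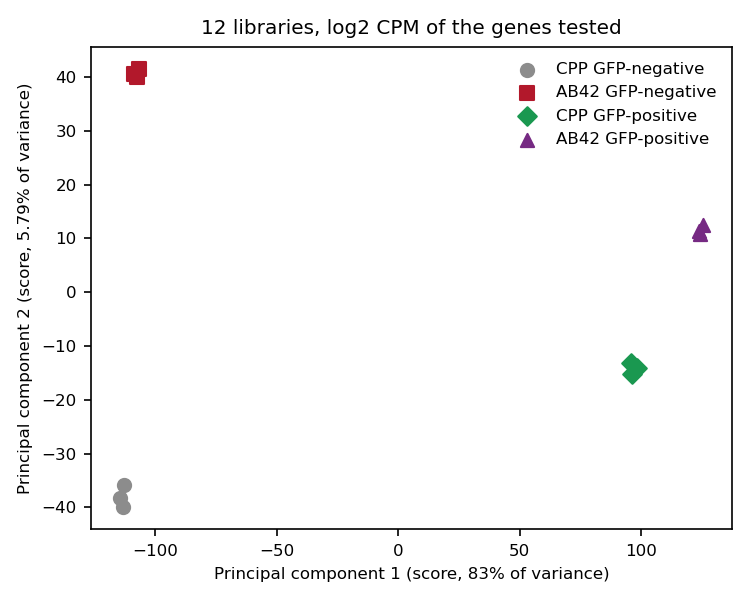
Scores of the 12 libraries on the first 2 principal components of the log2 CPM values, with 3 libraries per group. The horizontal axis carries 83% of the variance and separates the fractions, and the vertical axis carries 5.79% and separates AB42 from CPP.

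The comparison of the fractions after CPP asks what the sort separated in control brains. The reporter gene her4.1 (ENSDARG00000056732, GRCz10 chromosome 23, 21526006 to 21527063), a Notch target of radial glia, stood at 32.3 ± 1.49 CPM in GFP-negative and 2277 ± 176 CPM in GFP-positive cells, 70.6-fold higher (log2 6.14 ± 0.07 SE, edgeR adjusted p = 5.74e-40). Radial glia genes followed it: the glutamate transporter SLC1A2 rose 76.2-fold, her4.2 68.3-fold, the intermediate filament GFAP 59.1-fold, the fatty acid binding protein FABP7 (ENSDARG00000007697) 44.9-fold and S100B 33.2-fold. Near-identical her4 copies may share reads, which was not tested. The largest rises by the naming rule included arf4b (3.86 ± 0.983 to 1553 ± 89.9 CPM, 417-fold), gpc5b (302-fold), LIX1 (257-fold), the growth factor carrier fgfbp3 (208-fold) and the transcription factors PTF1A (167-fold) and rx3 (158-fold). By the same rule slc52a3-2a and her8.2 belong here, with 1 and 3 counts in all 3 GFP-negative libraries against 12 ± 1.09 and 13.7 ± 1.94 CPM in GFP-positive cells. The largest falls by the rule began with PMCH, the precursor of melanin-concentrating hormone (ENSDARG00000073959, chromosome 4, 17347581 to 17349777), which stood at 29.6 ± 2.55 CPM in GFP-negative cells and had 4 counts in all 3 GFP-positive libraries. It was followed by pmchl (53.8-fold), GAD1 (ENSDARG00000093411, 31.1-fold), FAT2 (27.2-fold), UCN3 (27.0-fold), pth2 (26.8-fold) and GABRA6 (26.7-fold).

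Of 36 radial glia genes 33 were higher in GFP-positive cells after CPP and 2 were lower, with a median log2 fold change of 4.21 (camera adjusted p = 8e-23). Synapse genes were lower in 54 of 57 and higher in 1 (median -2.50, camera adjusted p = 5.98e-22). The vesicle fusion gene SNAP25 (ENSDARG00000020609) was 10.6-fold lower. Mature neuron genes were lower in 45 of 48 and higher in 3 (median -2.54, camera adjusted p = 1.07e-18). Leukocyte genes fell in 23 of 27 and rose in 2 (median -2.53, camera adjusted p = 3e-06). Oligodendrocyte genes fell in 19 of 23 and rose in 2 (median -0.99, camera adjusted p = 4.65e-06), with the myelin gene mbpa 3.49-fold lower. Cilia genes rose in 34 of 39 and fell in 2 (median 2.02, camera adjusted p = 7.59e-06), with the ciliogenesis regulator FOXJ1 6.97-fold higher. ER stress genes rose in 30 of 37 and fell in 3 (median 1.13, camera adjusted p = 7.92e-10), with DDIT3 4.92-fold higher. Cholesterol synthesis genes rose in 21 of 27 (2 fell, camera adjusted p = 4.19e-05). Cell cycle genes rose in 43 of 54 (2 fell, camera adjusted p = 4.19e-05). Notch genes rose in 24 of 34 and fell in 5 (24 and 6 adjusted over the list alone, camera adjusted p = 6.7e-05). Wnt genes rose in 25 of 43 and fell in 9 (camera adjusted p = 0.00225), with WNT7A 14.1-fold higher.

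A further 12 lists passed after CPP with the preset correlation but not with an estimated one. Ribosomal protein genes rose in 82 of 83 (median 0.61, camera adjusted p = 2.07e-13, 0.314 with an estimated correlation). Immediate early genes rose in 32 of 52 with 14 lower (camera adjusted p = 2.73e-05, 0.0679 with an estimated correlation) and interferon and antigen presentation genes in 30 of 41 with 8 lower (4.19e-05, 0.0987). Reactive glia genes rose in 27 of 41 with 10 lower (camera adjusted p = 4.19e-05, 0.119 with an estimated correlation), and apoptosis genes in 25 of 40 with 8 lower (0.00631, 0.106). Microglia genes fell in 31 of 53 and rose in 9 (camera adjusted p = 0.00105, 0.301 with an estimated correlation), endothelium genes fell in 31 of 45 and rose in 9 (0.0109, 0.0914) and erythrocyte genes fell in 10 of 11 and rose in 1 (0.0285, 0.119). BMP and Id genes (camera adjusted p = 0.0289, 0.119 with an estimated correlation) and inflammatory genes (0.0426, 0.132) passed upwards as well, but their medians changed sign with library totals, and so did those of the last 2 lists. Oxidative phosphorylation genes rose in 69 of 94 and fell in 9 (camera adjusted p = 2.73e-05, 0.496 with an estimated correlation), but their median went from 0.45 to -0.035 with library totals. Chaperone genes rose in 23 of 37 and fell in 9 (camera adjusted p = 0.000165, 0.119 with an estimated correlation, median 0.44, or -0.042 with library totals). The neurogenic, IL4-STAT6, amyloid processing, neurotrophin and matrix lists did not pass (camera adjusted p = 0.252, 0.252, 0.373, 0.625 and 0.937).

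Of 20237 genes tested, 14782 (73%) passed the threshold between the fractions after CPP, 7517 higher and 7265 lower in GFP-positive cells, with 8731 changed at least 2-fold. All 3 libraries of one fraction lay beyond the 3 of the other for 74.1% of genes, against 10% by chance. With library totals only, 4630 genes were higher and 10673 lower and the median of all genes shifted by -0.48, so how the calls divide between higher and lower depends on the scaling.

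The comparison of AB42 with CPP in GFP-positive cells asks what differed between the injections in the radial glia fraction at 48 hours. The time of day at which the brains were taken is not given in the sources used here. A difference in it, which the clock genes below leave open, cannot be told apart from an effect of AB42. The largest rise by the rule was F13A1, a transglutaminase that cross-links fibrin (ENSDARG00000045453, chromosome 24, 2499153 to 2519579), from 1.21 ± 0.549 to 12.5 ± 0.630 CPM, 10.1-fold (log2 3.34 ± 0.21 SE, edgeR adjusted p = 1.06e-14). The cytokine clcf1 (ENSDARG00000076140, chromosome 14, 21725196 to 21741151) rose 9.48-fold from 0.697 ± 0.356 to 6.59 ± 1.95 CPM (edgeR adjusted p = 6.31e-10). Its secretion partner crlf1a rose 4.66-fold from 4.45 ± 1.78 to 20.6 ± 0.321 CPM. Other rises named by the rule were the tendon transcription factor SCX (4.66-fold), kng1 (4.53-fold), HOXA3 (4-fold) and the tubulin tubb6 (3.84-fold). The largest fall by the rule was the IgM heavy chain ighm (ENSDARG00000096355, chromosome 3, 33833739 to 33965713), from 11.7 ± 1.59 to 0.344 ± 0.173 CPM, 34.9-fold lower (edgeR adjusted p = 2.04e-17). It was followed by cbln12 (8.40-fold). Among epithelial genes the keratin krt5 was 8.30-fold lower (102 ± 12.3 to 12.5 ± 3.66 CPM, edgeR adjusted p = 2.15e-21) and the tight junction genes cldnb and cldna each 8.37-fold. The other large falls were the granulocyte factor csf3b (6.79-fold), the clock gene PER1 (ENSDARG00000056885, 26.9 ± 4.33 to 4.01 ± 0.419 CPM, 6.67-fold) and the cytokine il1b (6.42-fold).

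Proliferation genes rose in the GFP-positive fraction: PCNA, the sliding clamp of DNA replication, went from 93.4 ± 3.65 to 144 ± 3.80 CPM (1.54-fold, edgeR adjusted p = 5.91e-09). The marker mki67 went from 21.6 ± 1.46 to 35.4 ± 4.4 CPM (1.64-fold, edgeR adjusted p = 6.05e-05), while RRM1 and NCAPG rose 1.88-fold and 2.17-fold. Of 54 cell cycle genes 34 rose and 1 fell (40 and 1 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 4.69e-19). Radial glia genes split by gene. GFAP rose 1.54-fold from 190 ± 7.79 to 293 ± 14.9 CPM (edgeR adjusted p = 1.85e-09). In contrast her4.1 fell by 0.27 on the log2 scale (2277 ± 176 to 1892 ± 120 CPM, edgeR adjusted p = 0.00023). FABP7 (ENSDARG00000007697) fell by 0.20, glutamine synthetase (GLUL) by 0.47, MDK (ENSDARG00000020708) by 0.49 and the gap junction gene GJA1 by 0.33. S100B was not past the threshold (edgeR adjusted p = 0.253). The 36 genes of that list gave 7 higher and 15 lower (8 and 15 adjusted over the list alone, median -0.070, camera adjusted p = 0.00567, 0.397 with an estimated correlation). With library totals the median was 0.025 with 10 higher and 12 lower. Motile cilia genes rose in 5 of 39 with 1 lower (4 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.00427). FOXJ1 rose from 83.9 ± 3.51 to 160 ± 3.56 CPM (1.91-fold, edgeR adjusted p = 2.25e-12). Of 41 reactive glia genes 14 rose and 5 fell (21 and 6 adjusted over the list alone, camera adjusted p = 9.77e-08, 0.0796 with an estimated correlation). Among them were the growth factor hbegfa (2.41-fold), ANXA2 (1.83-fold) and the cytokine feedback inhibitor SOCS3 (203 ± 3.11 to 331 ± 7.34 CPM, 1.63-fold).

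Protein folding genes rose as well. Of 37 chaperone genes 25 rose and 1 fell (27 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 8.78e-34). HSPA4 rose 2.65-fold (99.3 ± 3.50 to 263 ± 4.07 CPM), HSPA8 1.99-fold and HSP90AA1 1.59-fold. Of 37 ER stress genes 14 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 8.06e-11). The ER chaperone HSPA5 rose 1.86-fold (1671 ± 58.0 to 3111 ± 28.6 CPM, edgeR adjusted p = 4.64e-18), ATF3 1.72-fold and HSP90B1 1.58-fold. Immediate early genes rose in 24 of 52 and fell in 9 (26 and 11 adjusted over the list alone, camera adjusted p = 5.16e-08), with NR4A3 1.91-fold higher. Their median was 0.13 and their mean -0.0030, so the sign of the shift rests on the measure.

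Genes of neurons, myelin and immune cells were lower in the GFP-positive fraction after AB42. Mature neuron genes fell in 33 of 48 and rose in 1 (37 and 1 adjusted over the list alone, median -0.75, camera adjusted p = 1.19e-16). The GABA synthesis gene GAD1 (ENSDARG00000027419) was 2.79-fold lower (25.7 ± 1.16 to 9.31 ± 1.22 CPM). Synapse genes fell in 37 of 57 and rose in 2 (43 and 2 adjusted over the list alone, median -0.66, or -0.65 with a gene at 0 counts set to its bound, camera adjusted p = 1.19e-14). SNAP25 was 2.28-fold (ENSDARG00000020609) and 2.83-fold (ENSDARG00000058117) lower. Oligodendrocyte genes fell in 10 of 23 and rose in 0 (12 and 0 adjusted over the list alone, median -0.32, camera adjusted p = 3.04e-05), with mbpa 1.54-fold lower (1686 ± 88.5 to 1098 ± 83.5 CPM). Of 41 interferon and antigen presentation genes 24 fell and 0 rose (27 and 1 adjusted over the list alone, median -0.41, camera adjusted p = 2.4e-14). The class II gene mhc2dab was 3.05-fold (156 ± 2.90 to 51.4 ± 5.5 CPM) and the invariant chain cd74a 1.92-fold lower. Leukocyte genes fell in 9 of 27 and rose in 1 (11 and 1 adjusted over the list alone, median -0.91, or -0.77 with zero groups at their bound, camera adjusted p = 0.0321, 0.0796 with an estimated correlation). Without CPP GFP-positive replicate 1 the list no longer passed (camera adjusted p = 0.0528). Its member igic1s1, an immunoglobulin light chain, had 2 counts in all 3 AB42 libraries against 1.87 ± 0.340 CPM after CPP. Of 53 microglia genes 17 fell and 3 rose (19 and 4 adjusted over the list alone, median -0.12, camera adjusted p = 0.0168, 0.497 with an estimated correlation). With library totals 9 were higher and 10 lower, with a median of -0.021. Oxidative phosphorylation genes fell in 46 of 94 and rose in 2 (60 and 3 adjusted over the list alone, median -0.26, camera adjusted p = 4.05e-12, 0.375 with an estimated correlation), among them ndufa4b, 1.95-fold lower. Ribosomal protein genes rose in 7 of 83 and fell in 2 (camera adjusted p = 0.00703, 0.759 with an estimated correlation), and the direction turned without CPP GFP-positive replicate 2 (0.78). Of 40 apoptosis genes 8 rose and 3 fell (camera adjusted p = 0.0168, 0.149 with an estimated correlation), among them CCNG1, 1.29-fold higher.

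Interleukin-4 signalling genes were examined because the fixed genes include its ligand and receptor. The ligand il4 was not past the threshold in GFP-positive cells (0.531 ± 0.203 and 0.502 ± 0.233 CPM, edgeR adjusted p = 0.945). The floor of 3 counts was 0.237 to 0.326 CPM in these libraries, so at this level a change could be missed. Its receptor il4r.1 rose 1.84-fold from 23.5 ± 2.96 to 43.2 ± 6.07 CPM (edgeR adjusted p = 1.01e-07) and stat6 1.38-fold (edgeR adjusted p = 0.0108, 0.082 without CPP GFP-positive replicate 1). The IL4-STAT6 list gave 5 higher and 3 lower of 16 (median 0.15, mean -0.057, camera adjusted p = 0.0537). Genes fixed by name that did not pass were apoeb (edgeR adjusted p = 0.345), ELAVL3 (0.593), appa (0.699), APP (0.0561), the FABP7 copy ENSDARG00000034650 (0.154) and NGFR (0.833 and 0.24 for its 2 genes). MPEG1 (ENSDARG00000055290) was 1.17-fold lower (edgeR adjusted p = 0.0369, 0.0513 with RLE size factors) and BDNF 1.88-fold lower (edgeR adjusted p = 0.0373, 0.0541 with DESeq2). A further 2 MPEG1 genes stayed under the count filter with 78 and 61 counts over all libraries. Lists that did not pass were neurogenic progenitors (2 of 34 higher and 13 lower, 3 and 15 adjusted over the list alone, camera adjusted p = 0.0572). Neither did Wnt (camera adjusted p = 0.116), cholesterol synthesis (0.153), BMP and Id genes (0.274) or inflammatory cytokines (12 of 49 higher and 13 lower, 14 and 14 adjusted over the list alone, 0.488). The amyloid processing (3 of 32 higher and 4 lower, camera adjusted p = 0.512), Notch (5 of 34 higher and 6 lower, 0.638) and neurotrophin lists (0 of 12 higher and 1 lower, 0.638) were not past the threshold, nor were erythrocytes (0.703), endothelium (0.784) and matrix (0.84).

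Of 20237 genes 3779 (18.7%) passed the threshold between AB42 and CPP in GFP-positive cells, 1256 higher and 2523 lower, with 134 and 732 of them changed at least 2-fold. Libraries of the 2 injections did not overlap for 32% of genes, against 10% by chance. With library totals only, 2112 genes were higher and 1769 lower. A fit of only the 6 libraries, in which the filter kept 17918 genes, gave 1594 and 1792. The excess of lower genes therefore depends on the scaling and on the libraries and genes fitted. Of the 2523 lower genes 59.8% were higher in GFP-negative than in GFP-positive cells of CPP brains, and of the 732 at least 2-fold lower 78.8% were, against 35.9% of all genes. The same share was 20.8% of the 1256 higher genes and 34.3% of the 134 at least 2-fold higher. F13A1, the largest rise by the rule, also rose in GFP-negative cells, to a higher level. Whether RNA carried over from GFP-negative cells contributed to the rises was not tested. Splits of the same 6 libraries that mix the injections called 0 genes in edgeR (up to 1813 with an unadjusted p under 0.05), but up to 12 lists in camera where the injections gave 16. Such splits keep part of the difference between the injections and widen the spread within the groups. Neither count therefore shows what chance alone would give, and a list result should not be read alone.

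**Figure D2:**
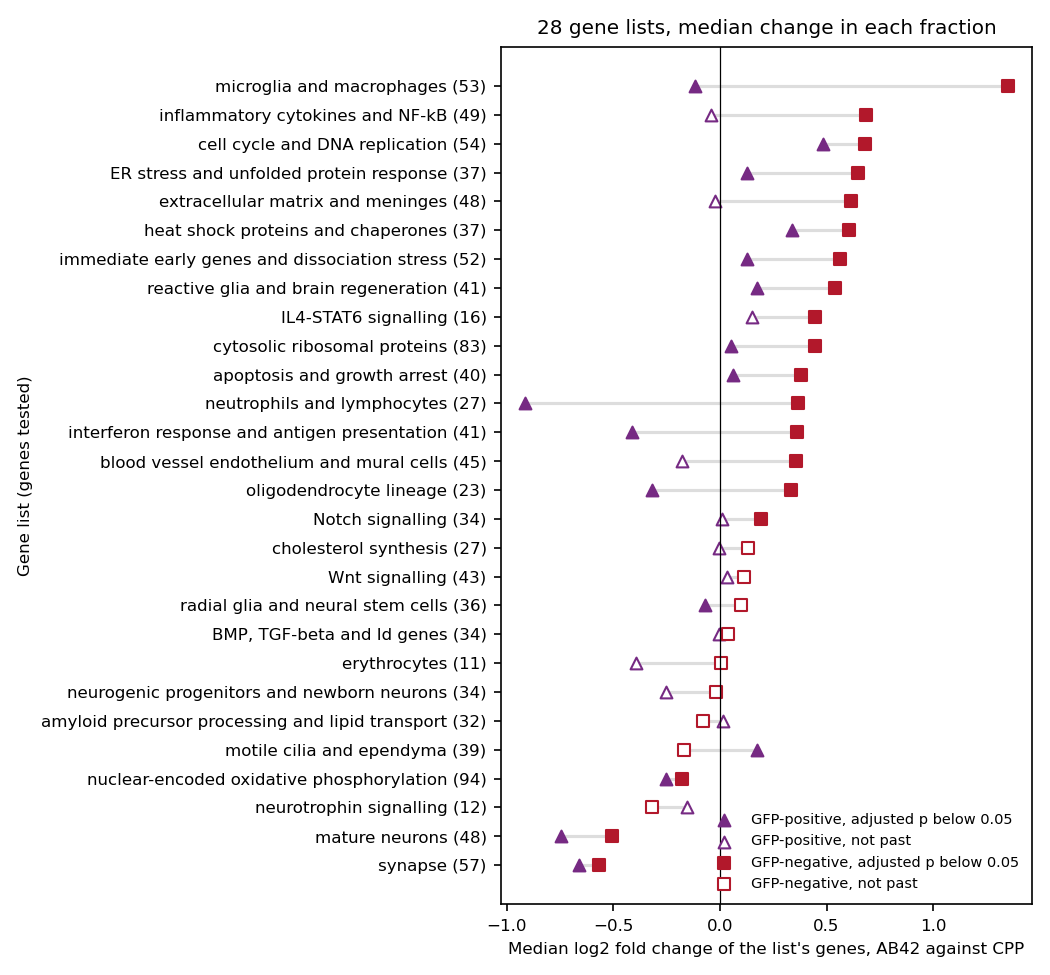
Median log2 fold change, AB42 against CPP, of the genes in each of 28 lists in GFP-positive (triangles) and GFP-negative cells (squares), with the number of genes tested in brackets and filled symbols for lists past the threshold in camera. The microglia list lies at 1.35 in GFP-negative and -0.12 in GFP-positive cells, while the synapse and mature neuron lists lie below 0 in both.

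The comparison of AB42 with CPP in GFP-negative cells asks what differed between the injections in the rest of the brain: neurons, oligodendrocytes, microglia and other cells. These cell types were not separated, so a changed share of a cell type cannot be told apart from changed expression within it. F13A1 again rose most by the rule, from 2.26 ± 0.307 to 34.8 ± 2.85 CPM (log2 fold change 3.92 ± 0.17 SE, edgeR adjusted p = 1.16e-20). PLIN2, which coats lipid droplets (ENSDARG00000042332, chromosome 15, 17094451 to 17112800), rose 7.86-fold from 27.8 ± 3.80 to 218 ± 0.953 CPM (edgeR adjusted p = 4.37e-26). Further rises were the complement gene c3a.4 (9.04-fold), mfap4.10 (8.98-fold), the kinase gene sgk2b (8.90-fold), the microglial purine receptor P2RY12 (0.784 ± 0.337 to 6.51 ± 1.06 CPM, 8.30-fold), lgals3bp.3 (7.66-fold) and the chemokine ccl34a.4 (7.33-fold). The largest falls by the rule were camk1ga (7.59 ± 0.924 to 1.22 ± 0.199 CPM, 6.19-fold lower), PER1 (ENSDARG00000056885, 5.08-fold), s100s (4.22-fold), ceruloplasmin (CP, 3.89-fold), dbpb, an output gene of the circadian clock (108 ± 8.89 to 28.3 ± 3.65 CPM, 3.80-fold), smu1b (3.71-fold), GOLGA7B (3.55-fold) and cbln12 (3.39-fold).

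Microglia and macrophage genes rose in 47 of 53 and none (0) fell in GFP-negative cells after AB42 (median 1.35, camera adjusted p = 9.62e-44). The lipid carrier apoeb (ENSDARG00000040295, chromosome 16, 24045712 to 24048429) rose 4.03-fold from 868 ± 59.2 to 3498 ± 93.4 CPM (edgeR adjusted p = 1.15e-27). The galectin-related gene lgals3bp.1 rose 6.58-fold, lgals9l1 3.64-fold and MPEG1 (ENSDARG00000055290) 2.24-fold. Inflammatory genes rose in 32 of 49 and fell in 6 (33 and 6 adjusted over the list alone, median 0.69, camera adjusted p = 2.62e-10). The chemokine ccl34b.1 rose 4.49-fold and FOSL1 3.21-fold. The cytokine il4 (ENSDARG00000087909, chromosome 14, 23702323 to 23704580) rose 5.09-fold (2.16 ± 0.479 to 11.3 ± 0.572 CPM, edgeR adjusted p = 3.66e-11). The related cytokine il13 rose 6.01-fold (2.47 ± 0.790 to 15 ± 1.14 CPM, edgeR adjusted p = 3.49e-12). Their receptor genes il4r.1 and il13ra1 rose 3.67-fold and 2.46-fold, and stat6 2.18-fold. The IL4-STAT6 list rose in 8 of 16 and fell in 0 (median 0.45, camera adjusted p = 7.32e-05). Leukocyte genes rose in 8 of 27 and fell in 0 (median 0.37, camera adjusted p = 0.000703), with the matrix proteases mmp13a 3.93-fold and MMP9 2.31-fold higher. Of 41 interferon and antigen presentation genes 21 rose and 1 fell (median 0.36, camera adjusted p = 1.48e-05, 0.0711 with an estimated correlation), with cd74a 2.1-fold higher.

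Stress and proliferation genes rose too. ER stress genes were higher in 28 of 37 and lower in 0 (median 0.65, camera adjusted p = 9.3e-16). HSPA5 rose 3.21-fold (799 ± 9.44 to 2568 ± 115 CPM, edgeR adjusted p = 8.97e-27), HSP90B1 2.62-fold and XBP1 1.90-fold. Of 37 chaperone genes 28 rose and 4 fell (29 and 4 adjusted over the list alone, median 0.61, camera adjusted p = 7.4e-17). HSPA4 rose 3.70-fold and hsp70.3 1.84-fold, though hsp70 copies may share reads, which was not tested. Immediate early genes rose in 38 of 52 and fell in 3 (41 and 4 adjusted over the list alone, median 0.56, camera adjusted p = 1.79e-19). Cell cycle genes rose in 40 of 54 and fell in 0 (42 and 0 adjusted over the list alone, median 0.68, camera adjusted p = 4.22e-09). TOP2A rose 2.48-fold (10.7 ± 1.68 to 26.4 ± 1.81 CPM), mki67 1.96-fold and PCNA 1.49-fold. Matrix genes rose in 27 of 48 and fell in 3 (28 and 3 adjusted over the list alone, median 0.62, camera adjusted p = 2.66e-05), with TIMP2 2.64-fold and ALDH1A2 2.68-fold higher. Endothelium genes rose in 19 of 45 and fell in 1 (camera adjusted p = 0.00069), with pecam1a 4.90-fold higher. Oligodendrocyte genes rose in 13 of 23 and fell in 0 (median 0.33, camera adjusted p = 1.83e-05). Reactive glia genes rose in 24 of 41 and fell in 4 (27 and 4 adjusted over the list alone, median 0.54, camera adjusted p = 7e-06, 0.106 with an estimated correlation). HBEGF rose 3.95-fold and krt8 2.78-fold. Of 40 apoptosis genes 23 rose and 5 fell (23 and 7 adjusted over the list alone, camera adjusted p = 0.000937, 0.0557 with an estimated correlation), with baxb 2.89-fold higher. Ribosomal protein genes rose in 82 of 83 (1 fell, median 0.45, camera adjusted p = 3.55e-24, 0.188 with an estimated correlation).

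Neuronal genes were lower in the GFP-negative fraction after AB42. A smaller share of neurons and lower expression within neurons could both give this, and they were not tested apart. Synapse genes were lower in 46 of 57 and higher in 1 (48 and 1 adjusted over the list alone, median -0.57, camera adjusted p = 5.17e-22). SNAP25 (ENSDARG00000020609) was 1.77-fold lower (2217 ± 66.3 to 1255 ± 15 CPM). Mature neuron genes were lower in 35 of 48 and higher in 3 (37 and 4 adjusted over the list alone, median -0.50, camera adjusted p = 2.01e-15), with RBFOX3 2.22-fold and sncb 1.91-fold lower. The newborn neuron marker ELAVL3 was 1.23-fold lower (570 ± 13.4 to 464 ± 19.7 CPM) and BDNF 1.41-fold lower (edgeR adjusted p = 0.0203, 0.0873 without AB42 GFP-negative replicate 2). The amyloid precursor genes appa and APP fell by 0.43 and 0.46 on the log2 scale (edgeR adjusted p = 7.37e-08 and 1.1e-08). The neurotrophin receptor NGFR rose 3.62-fold in its copy ENSDARG00000089223 (3.57 ± 0.756 to 12.7 ± 1.49 CPM, edgeR adjusted p = 2.68e-09) and 1.36-fold in ENSDARG00000088708 (edgeR adjusted p = 0.00501, 0.0753 with library totals). Oxidative phosphorylation genes fell in 35 of 94 and rose in 3 (37 and 3 adjusted over the list alone, median -0.18, camera adjusted p = 5.65e-05, 0.567 with an estimated correlation). Notch genes rose in 13 of 34 and fell in 0 (camera adjusted p = 0.0454, 0.163 with an estimated correlation), with NRARP 1.61-fold and mfng 1.96-fold higher. Of the glial genes fixed by name, GFAP rose 1.45-fold from a low level (3.20 ± 0.121 to 4.64 ± 0.714 CPM, edgeR adjusted p = 0.00404, 0.0576 with limma voom). In these cells her4.1 (edgeR adjusted p = 0.0647), FABP7 (0.0862 and 0.101 for its 2 genes) and S100B (0.615) were not past the threshold. Lists that did not pass were radial glia (13 of 36 higher and 2 lower, camera adjusted p = 0.112) and neurogenic progenitors (10 of 34 higher and 11 lower, 0.272). The same held for neurotrophins (camera adjusted p = 0.119), cholesterol synthesis (0.131), Wnt (0.145), BMP and Id genes (0.752), erythrocytes (0.752), amyloid processing (0.752) and cilia (0.83).

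In GFP-negative cells 7733 of 20237 genes (38.2%) passed the threshold, 4239 higher and 3494 lower, with 1239 and 358 changed at least 2-fold. Libraries of the 2 injections did not overlap for 48.1% of genes, against 10% by chance. With library totals only, 3191 genes were higher and 5463 lower and the median of all genes shifted by -0.13. Other splits of the 6 libraries called 0 genes in edgeR (up to 726 with an unadjusted p under 0.05), but up to 17 lists in camera where the injections gave 19.

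**Figure D3:**
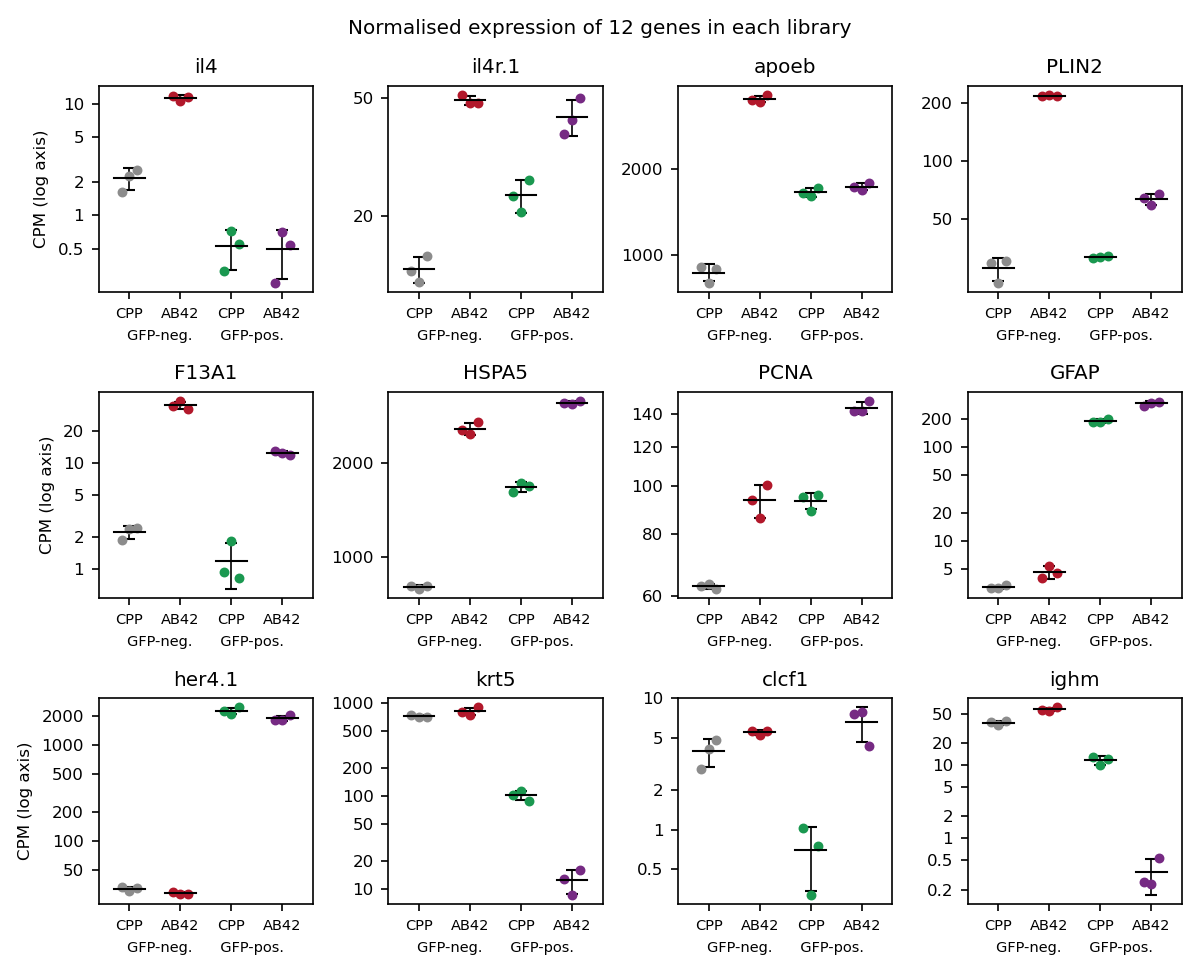
CPM of 12 genes in each library on a logarithmic axis, with 3 points per group, a horizontal bar at the mean and whiskers of 1 SD. The 3 AB42 libraries of il4, apoeb and PLIN2 lie above all others in GFP-negative cells, and those of krt5 and ighm lie below all others in GFP-positive cells.

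The difference between the 2 AB42 effects asks which genes responded differently in the 2 fractions. Across genes, which are not independent replicates, the 2 effects correlated weakly (Pearson 0.195, Spearman 0.229). Genes past the threshold in both fractions rose in both in 731 cases and fell in both in 1055 cases, against 263.1 and 435.6 if the calls were independent. A further 71 rose in GFP-positive and fell in GFP-negative cells, and 457 did the opposite. All of those 528 opposite genes also passed the test of the difference, which opposite calls in the same fit make nearly certain, so it is no separate support. Microglia genes differed most, lower in 48 of 53 for the difference and higher in 0 (50 and 1 adjusted over the list alone, median -1.77, camera adjusted p = 3.81e-54). Among them apoeb differed by -1.94 ± 0.07 SE (edgeR adjusted p = 4.29e-22), having risen past the threshold only in GFP-negative cells. The cytokine il4 (log2 difference -2.42, edgeR adjusted p = 0.00123), its receptor il4r.1 (-0.999, edgeR adjusted p = 5.58e-06) and stat6 (-0.66, edgeR adjusted p = 0.00652, 0.0793 with library totals) rose more in GFP-negative cells. The level of il4 in GFP-positive cells was close to the floor of 3 counts, so the size of its difference is uncertain. The difference of il13 was not past the threshold (edgeR adjusted p = 0.237). The largest positive differences by the rule were PMCH (3.31, edgeR adjusted p = 0.000172), clcf1 (2.79, edgeR adjusted p = 1.71e-06), ensaa (2.19) and col7a1l (2.17). The largest negative ones were the T-cell regulator tbx21, cldn7b, ighm (-5.74, edgeR adjusted p = 4.83e-18) and itln1. Of these tbx21, cldn7b and itln1 had 0, 2 and 1 counts in all AB42 GFP-positive libraries, and PMCH had 4 in all CPP GFP-positive libraries, so the size of these differences depends on the prior count. The amyloid precursor genes appa (0.47, edgeR adjusted p = 2.4e-05) and APP (0.31, edgeR adjusted p = 0.00364) had positive differences. They fell in GFP-negative cells, and APP missed the threshold narrowly in GFP-positive cells (log2 fold change -0.15, edgeR adjusted p = 0.0561). No difference was found for her4.1 (edgeR adjusted p = 0.409), GFAP (0.784), mki67 (0.361) or PCNA (0.777, but 0.0202 with library totals).

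Lists with a lower effect in GFP-positive cells were immediate early genes (36 of 52 lower and 2 higher, 38 and 3 adjusted over the list alone, camera adjusted p = 6.66e-17) and interferon and antigen presentation (25 of 41 and 0, 29 and 0 adjusted over the list alone, 1.74e-15). ER stress (20 of 37 lower and 0 higher, camera adjusted p = 1.06e-10) and inflammatory cytokines (27 of 49 and 4, 31 and 4 adjusted over the list alone, 5.74e-10) did likewise. The same held for oligodendrocytes (12 of 23 lower and 0 higher, 13 and 0 adjusted over the list alone, camera adjusted p = 4.34e-09), leukocytes (15 of 27 and 0, 16 and 0 adjusted over the list alone, 0.000126) and matrix (18 of 48 and 3, 20 and 3 adjusted over the list alone, 0.00198). With an estimated correlation 6 further lists lost their call. They were ribosomal proteins (73 of 83 lower, camera adjusted p = 1.82e-20, 0.329 with an estimated correlation), chaperones (17 of 37 lower and 4 higher, 23 and 4 adjusted over the list alone, 0.000142, 0.144) and endothelium (15 of 45 lower, 0.00361, 0.0538). The others were radial glia (15 of 36 lower, 17 and 1 adjusted over the list alone, camera adjusted p = 0.0101, 0.463 with an estimated correlation), IL4-STAT6 (8 of 16 lower, 9 adjusted over the list alone, 0.0126, 0.0538) and cilia, the only list with a higher effect in GFP-positive cells (median 0.39; 3 of 39 higher and 3 lower, 0.0254, 0.0696). The cilia list also lost its call in cameraPR and fry (adjusted p = 0.0646 and 0.0648) and without any 1 of 4 GFP-negative libraries (camera adjusted p = 0.0531 to 0.0637). The radial glia median of -0.21 became 0.016 with library totals, and the chaperone median went from -0.23 to -0.0015 with 7 genes higher and 6 lower. Mature neurons (camera adjusted p = 0.088), synapse (0.598), cell cycle (0.533), reactive glia (0.101), apoptosis (0.145), oxidative phosphorylation (0.736) and amyloid processing (0.768) were not past the threshold. The fry test did pass mature neurons (adjusted p = 5.1e-06), apoptosis (0.000428), amyloid processing (0.00101), reactive glia (0.00486) and cell cycle (0.00709), all downwards, so a difference is not ruled out. For apoptosis, amyloid processing and cell cycle genes that direction depends on the scaling, as their medians were 0.0068, 0.12 and 0.040 with library totals. The medians of mature neurons and reactive glia stayed negative but shrank, from -0.256 to -0.026 and from -0.275 to -0.047.

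The test of the difference called 4439 genes, 1105 with a higher and 3334 with a lower effect in GFP-positive cells. With library totals only, the split was 3248 to 2109 and the median of all genes shifted by 0.23, so its direction depends on the scaling. Of 100 ways to split the injections within each fraction, 2 called as many genes, the real one and the one that swaps the injections in 1 fraction, and 11 passed as many lists in camera.

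**Figure D4:**
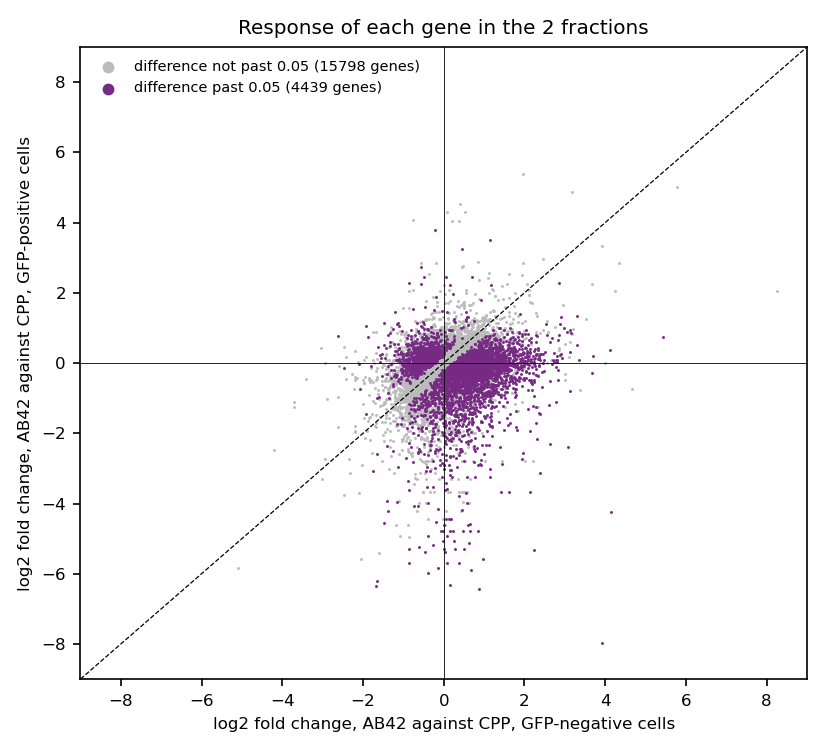
Log2 fold change of each of 20237 genes, AB42 against CPP, in GFP-negative (horizontal) and GFP-positive cells (vertical), with the 4439 genes whose effects differ past the threshold in purple and the line of equal effects dashed. Purple points lie mostly below the dashed line, as 3334 of the 4439 genes do.

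The average of the 2 AB42 effects asks what differed between the injections on average, to which either fraction alone can lead. Genes such as F13A1, HSPA4, HSPA5 and PCNA, which rose in each fraction, and SNAP25, which fell in each, belong to it. Chaperone genes rose in 28 of 37 and fell in 3 on average (median 0.55, camera adjusted p = 8.92e-26), and ER stress genes rose in 28 of 37 and fell in 0 (7.39e-20). Cell cycle genes rose in 46 of 54 and fell in 1 (49 and 1 adjusted over the list alone, camera adjusted p = 2.07e-18), immediate early genes rose in 35 of 52 and fell in 5 (37 and 6 adjusted over the list alone, 1.4e-20) and microglia genes rose in 41 of 53 and fell in 3 (1.32e-24). Synapse genes fell in 46 of 57 and rose in 1 (50 and 2 adjusted over the list alone, camera adjusted p = 1.09e-21) and mature neuron genes fell in 38 of 48 and rose in 2 (40 and 2 adjusted over the list alone, 1.31e-18). Inflammatory (28 of 49 higher and 11 lower, camera adjusted p = 1.16e-05), apoptosis (22 of 40 higher and 3 lower, 8.87e-05), IL4-STAT6 (7 of 16 higher and 1 lower, 0.002) and matrix genes (15 of 48 higher and 3 lower, 0.00314) passed upwards. Microglia genes passed upwards in GFP-negative cells (47 higher and 0 lower, median 1.35) and went the other way in GFP-positive cells (3 higher and 17 lower, median -0.12). Inflammatory (12 higher and 13 lower), IL4-STAT6 (5 and 3) and matrix genes (4 and 5) did not pass in GFP-positive cells, so these averages come mainly from GFP-negative cells. Ribosomal protein genes (70 of 83 higher and 1 lower, camera adjusted p = 1.41e-22, 0.243 with an estimated correlation), oxidative phosphorylation genes (1 of 94 higher and 59 lower, 7.59e-11, 0.391) and reactive glia genes (26 of 41 higher and 5 lower, 5.54e-09, 0.0603) passed with the preset but not with an estimated correlation. In edgeR 7260 genes (35.9%) passed, 3412 higher and 3848 lower, and 337 and 454 of them changed at least 2-fold.

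The comparison of the fractions after AB42 asks whether the sort separated the same cells in brains with AB42. It did for radial glia genes: her4.1 was 65.4-fold and GFAP 62.5-fold higher in GFP-positive cells, and SLC1A2 79.0-fold. The largest rises by the naming rule were acsl2 (1.95 ± 0.817 to 647 ± 58.5 CPM, 335-fold), gpc5b (308-fold), arf4b (258-fold), fgfbp3 (231-fold), rx3 (172-fold), the potassium channel KCNJ10 (171-fold) and LIX1 (164-fold), with PALMD at 2 counts in GFP-negative cells against 10.3 ± 1.22 CPM. Among the largest falls by the rule the T-cell gene tbx21 had 0 counts in AB42 GFP-positive cells and was at least 30.0-fold lower, and ighm was 171-fold lower (57.4 ± 3.15 and 0.344 ± 0.173 CPM). By the same rule itga2b, cldn7b, gpr55a, ccl38a.5 and itln1 had 1, 2, 1, 2 and 1 counts in those libraries against 14.2 ± 0.906, 22.7 ± 1.56, 11.4 ± 2.59, 14.8 ± 0.715 and 8.33 ± 0.481 CPM in GFP-negative cells. The cytokine genes il13 and il4 were 54.1-fold and 22.1-fold lower in GFP-positive cells, cd74a 8.34-fold, LCP1 9.55-fold and apoeb 2.02-fold, whereas apoeb had been 1.90-fold higher there after CPP. In GFP-positive cells il13 and il4 were close to the floor of 3 counts, so the size of their ratios is uncertain.

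Of 36 radial glia genes 33 were higher in GFP-positive cells after AB42 and 2 lower (median 3.90, camera adjusted p = 1.03e-22), and microglia genes were lower in 50 of 53 and higher in 1 (median -2.38, camera adjusted p = 1e-19). Synapse genes were lower in 52 of 57 (2 higher, median -2.54, or -2.49 with zero groups at their bound, camera adjusted p = 2.26e-17), mature neuron genes in 45 of 48 (3 higher, 8.13e-16) and oligodendrocyte genes in 20 of 23 (2 higher, 5.08e-08). Leukocyte genes were lower in 24 of 27 (0 higher, median -3.90, or -3.87 with zero groups at their bound, camera adjusted p = 1.31e-07), endothelium genes in 34 of 45 (8 higher, 0.00102) and IL4-STAT6 genes in 13 of 16 (1 higher, 0.00963). Cilia genes were higher in 35 of 39 (3 lower, camera adjusted p = 3.32e-07), ER stress genes in 31 of 37 (4 lower, 1.07e-06) and cell cycle genes in 39 of 54 (1 lower, 4.54e-05). Cholesterol synthesis genes were higher in 22 of 27 (3 lower, camera adjusted p = 0.000105), Notch genes in 20 of 34 (7 lower, 0.000596) and Wnt genes in 26 of 43 (8 lower, 0.000792). A further 6 lists passed upwards with the preset but not with an estimated correlation. Oxidative phosphorylation (camera adjusted p = 0.000125, 0.582 with an estimated correlation), reactive glia (0.000159, 0.171), ribosomal proteins (0.00124, 0.703), immediate early genes (0.00963, 0.232), BMP and Id genes (0.0105, 0.0824) and chaperones (0.0335, 0.38) made up these. With library totals the median changed sign for chaperones (0.079 to -0.175) and ribosomal proteins (0.21 to -0.048). Erythrocytes (camera adjusted p = 0.0635), apoptosis (0.0669), neurogenic progenitors (0.193), matrix (0.428), interferon and antigen presentation (0.497), inflammatory cytokines (0.714), amyloid processing (0.714) and neurotrophins (0.903) did not pass.

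After AB42 14908 genes (73.7%) passed between the fractions, 7286 higher and 7622 lower in GFP-positive cells, 8961 of them at least 2-fold, and the libraries did not overlap for 75.8% of genes against 10% by chance. With library totals only, 5452 were higher and 9280 lower, with a shift of the median of all genes of -0.25. Across genes, which are not independent replicates, the differences between the fractions after AB42 and after CPP correlated at a Pearson coefficient of 0.905, and the 2 comparisons share no library. In both comparisons of the fractions no other split called a gene in edgeR (0 past the threshold, up to 378 after CPP and 299 after AB42 with an unadjusted p under 0.05), while up to 20 and 17 lists passed in camera.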

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

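Each gene or list here was singled out because edgeR or camera found its AB42 effect to differ between GFP-positive and GFP-negative cells, and the values are log2 differences of the effects, GFP-positive minus GFP-negative. In all 4439 genes passed, 1105 with a positive and 3334 with a negative difference, but 3248 and 2109 with library totals, so the excess of negative differences depends on the scaling. The list medians were -1.77 for microglia and macrophages, -1.29 for leukocytes, -0.82 for IL4-STAT6 signalling, -0.77 for inflammatory cytokines, -0.76 for interferon response and antigen presentation, -0.72 for matrix and -0.69 for endothelium. They were -0.64 for oligodendrocytes, -0.47 for ER stress, -0.45 for immediate early genes, -0.42 for ribosomal proteins, -0.23 for chaperones, -0.21 for radial glia and 0.39 for cilia. The named genes reported here that passed follow by kind.

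Microglia and macrophage genes with a negative difference were lgals3bp.3 (-2.81), ccl34b.1 (-2.70), ccl34a.4 (-2.66), lgals3bp.1 (-2.62), P2RY12 (-2.18), lgals9l1 (-2.03), apoeb (-1.94), PLIN2 (-1.98), LCP1 (-1.53), MPEG1 (-1.39), grna.1 (-1.35) and CORO1A (-1.30). Genes of lymphocytes and other blood cells were tbx21 (-6.55), ighm (-5.74), itga2b (-5.23), igic1s1 (-4.78), gpr55a (-4.62), ccl38a.5 (-4.33), csf3b (-3.69), il1b (-2.83), mmp13a (-1.89), CCR9 (-1.57), tagapa (-1.29), GATA3 (-0.97) and srgn (-0.85), of which tbx21, itga2b, igic1s1, gpr55a and ccl38a.5 had at most 2 counts summed over the AB42 GFP-positive libraries, so the size of their difference depends on the prior count. Epithelial genes were cldn7b (-5.78), itln1 (-5.53), krt5 (-3.24), cldnb (-2.72), cldna (-2.63) and krt8 (-0.87), with 2 and 1 counts for cldn7b and itln1. Antigen presentation and interferon genes were mhc2dab (-2.31), cd74a (-2.01), cd74b (-2), mhc1uba (-1.49), isg15 (-0.80), irf9 (-0.54) and b2ml (-0.43). The interleukin-4 pathway gave il4 (-2.42, close to the floor in GFP-positive cells), il4r.1 (-0.999), il13ra1 (-0.97) and stat6 (-0.66). Oligodendrocyte genes were zwi (-1.07), mbpb (-0.84), mbpa (-0.82), plp1b (-0.68) and cldnk (-0.47).

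Vascular, blood and matrix genes were hbaa1 (-2.03), rgs5b (-1.92), pecam1a (-1.51), fli1rs (-1.28), TAGLN (-0.89), SPOCK3 (-0.24), ALDH1A2 (-1.62), TGFBI (-0.90) and TIMP2 (-0.40). Chaperone and ER stress genes were XBP1 (-0.92), HSPA5 (-0.79), HSP90B1 (-0.73), hsp70.1 (-0.57), hsp70.3 (-0.54), HSPA4 (-0.48), DDIT3 (-0.47), HSP90AA1 (-0.38) and HSPB1 (-0.23). Immediate early genes were FOSL1 (-1.11), JUNB (ENSDARG00000104773, -0.77), ZFP36L1 (ENSDARG00000021443, -0.73), ZFP36L1 (ENSDARG00000016154, -0.66), JUNB (ENSDARG00000074378, -0.56), CEBPD (-0.55), SOCS3 (-0.41), FOS (-0.39), NR4A3 (-0.29), ATF3 (-0.27) and GADD45B (-0.20). Genes of apoptosis, the cell cycle and regeneration were HBEGF (-2.46), pmaip1 (-1.57), fas (-1.29), baxb (-1.19), lgals2a (-0.99), kif11 (-0.73) and TOP2A (-0.64). Ribosomal and mitochondrial genes were COX5B (-1.04), RPS4Y2 (-0.60), RPL7L1 (-0.57), RPL3 (-0.51), RPSA2 (-0.42), COX4I2 (-0.40), RPL13 (-0.35) and RPL4 (-0.29). Glial, Notch and Wnt genes were mfng (-1.53), GLUL (-0.62), GJA1 (-0.57), NRARP (-0.43), MDK (ENSDARG00000036036, -0.43), WLS (-0.40), adam10a (-0.36), FABP7 (ENSDARG00000007697, -0.30), WNT7A (-0.28) and her4.2 (-0.21). The cilia gene RFX2 (-0.63) had a negative difference too. Neuronal genes were cbln12 (-1.31), FAT2 (-1.27), GAD1 (ENSDARG00000027419, -0.93), SNAP25 (ENSDARG00000058117, -0.70), atp1a3a (-0.53), SNAP25 (ENSDARG00000020609, -0.37) and STMN2 (-0.34). The neurotrophin receptor gave NGFR (ENSDARG00000089223, -2.36) and NGFR (ENSDARG00000088708, -0.50), and other genes were sgk2b (-2.31) and arf4b (-0.69).

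Genes with a positive difference were PMCH (3.31), clcf1 (2.79), ensaa (2.19), col7a1l (2.17), SCX (2.07), KCNJ10 (1.70), acsl2 (1.37), s100s (1.35), crlf1a (1.04), hbegfa (0.72), HSPA8 (0.56) and CCNG1 (0.31), with 4 counts for PMCH in all CPP GFP-positive libraries. The cilia genes ak8 (1.38) and FOXJ1 (0.73), the neuronal genes RBFOX3 (0.80) and ELAVL3 (0.24), the amyloid precursor genes appa (0.47) and APP (0.31), the clock output gene dbpb (0.48) and the ATP synthase gene ATP5F1A (0.23) belong here too.

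A first pattern is the fall of neuron, oligodendrocyte and leukocyte genes in GFP-positive cells after AB42, and its 3 tests were chosen after the result was seen. A single smaller share of GFP-negative cells of every kind in the AB42 sort would lower the ratio of the fractions by the same factor for all genes. This holds only where the signal in GFP-positive cells was all carry-over. The genes used were past the threshold as higher in GFP-negative cells after CPP, with at least 5 CPM there. The median difference was -0.26 for mature neurons (bootstrap 95% interval over genes -0.44 to -0.12) and -0.66 for oligodendrocytes. It was -1.38 for leukocytes, -1.67 for microglia and -1.80 for epithelium, a gap of 1.54. Whether radial glia express some of these genes was not tested, and the epithelial set was chosen after the result was seen. The gap therefore cannot exclude a single share. Scaling is excluded, since the neuron median was -0.65 with library totals. That AB42 lowered these genes inside radial glia stays open. The prediction set for it was that genes higher in GFP-positive cells of CPP brains are as frequent as among all genes, 37.1%. Their share was 9.02% of the genes at least 2-fold lower, above the 5% set to exclude it, and 27.5% of all lower genes. The test cannot decide, because neuron, oligodendrocyte and leukocyte genes were mostly higher in GFP-negative cells, wherever they fell. Carry-over that fell by a different factor for each cell type could give the same values and was not tested apart. The median GFP-positive level went from 46.2% to 13.4% of the GFP-negative level for microglia and from 16.1% to 11.8% for neurons. For microglia this ratio fell mainly because the GFP-negative level rose. The median change of the whole microglia list was 1.35 in GFP-negative and -0.12 in GFP-positive cells.

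A second pattern is the fall of clock genes in both fractions, the set of which was chosen after the result was seen. PER1 (ENSDARG00000056885), ciarta, NR1D1 and their phase fell in 14 of 19 genes in GFP-positive and 17 of 19 in GFP-negative cells (1 rose), with medians of -0.77 and -0.85 (camera adjusted p = 6.1e-19 and 3.42e-13). If the brains were taken at another time of day, genes of the opposite phase should be higher, a prediction written before their values were seen, and their medians were 0.66 in GFP-positive and 0.59 in GFP-negative cells (8 genes, 6 and 5 higher), which fits although 1, CLOCK (ENSDARG00000003631), was lower in GFP-negative cells. In GFP-negative cells that set lost its call with an estimated correlation (camera adjusted p = 0.0343, 0.221 with an estimated correlation), and an effect of AB42 on the clock itself would give the same values. A difference in time of day would bear on every comparison of AB42 with CPP. A lower glucocorticoid signal, tested after the result was seen on 5 genes not yet looked at, stays open: medians were -0.33 and -0.081, with 3 lower and 1 higher in GFP-positive but only 1 lower in GFP-negative cells, short of the 3 in each that it predicted.

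A further pattern is the rise of chaperone, unfolded protein and immediate early genes. Read sharing between hsp70 copies was not tested itself, but it is excluded as the cause of the list result by a test chosen after the result was seen: without those 4 genes the chaperone list still passed in both fractions (larger camera adjusted p = 1.02e-12). Stronger handling or dissociation of the AB42 brains should raise the core immediate early genes in both fractions, a prediction written before their values were seen. Their medians were 0.65 in GFP-negative cells (11 of 12 higher) and 0.093 in GFP-positive cells (4 higher and 2 lower). All 12 belong to the immediate early list whose rise is part of the pattern, so they give no separate support. A part may come from handling, and the question stays open because injection and handling cannot be told apart. An effect of AB42 itself on protein folding was not tested apart.

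Counts were also set against other ways to divide the libraries, predictions written before the data were examined. In each of the 4 direct comparisons the real division alone gave as many genes and as many lists (1 of 10 divisions), too few divisions to rule out chance. For the difference of the effects 2 of 100 divisions called as many genes, with 7260 for the highest other, which exchanges difference and average, and for the average 1 of 100 did. For the number of lists 11 of 100 divisions matched or passed the 14 lists of either. Divisions that mix the injections keep part of the AB42 difference and widen the spread within the groups. They therefore cannot say how many genes or lists chance alone would give, and chance is not ruled out for these list counts.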

How the results depend on the processing

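Which alternatives were tried is given with the processing; those without malat1 and the hsp70 genes were chosen after seeing the data. The 6 counts of genes stayed within 1.5 times under every alternative except the added 2-fold minimum, which by its construction left 866 and 1597 genes for AB42 against CPP in GFP-positive and GFP-negative cells, 8731 and 8961 for the fractions after CPP and AB42, 1653 for the difference and 791 for the average. Leaving out 1 library gave 2871 to 3478, 6708 to 7077, 14291 to 14481, 14340 to 14526, 3839 to 4382 and 6548 to 6940 genes in the same order, and 14 to 17, 18 to 19, 23 to 23, 20 to 20, 12 to 15 and 14 to 16 lists. Where a group keeps 2 libraries its spread is pooled with the others. Similar counts need not hold the same genes. With library totals 3214 of the 5357 genes called for the difference were also called in the main fit, and 6974 of 7248 for the average. An estimated correlation left 9 lists for AB42 against CPP in GFP-positive cells, 11 for the fractions after CPP and 8 for the difference, and fry passed 22 lists for the difference and 23 for the average; the cause was not tested. With an estimated correlation 40 list results lost their call. Of all 168 list results, called or not, 158 stayed on their side of the threshold in cameraPR and 127 in fry. Without the 4 hsp70 genes the chaperone list lost its call for the fractions after AB42 (camera adjusted p = 0.0669). Among results past the threshold in the main or the alternative test directions turned in 3 cases, and the cause was not tested: ribosomal proteins for AB42 against CPP in GFP-positive cells without CPP GFP-positive replicate 2 (camera adjusted p = 0.78, against 2.61e-08 without replicate 3 and 0.652 without AB42 GFP-positive replicate 3), and inflammatory cytokines and neurotrophins for the fractions after AB42 in fry (adjusted p = 4.45e-06 and 0.0393). No named gene turned its direction: of 379 gene results, called or not, 363 stayed on their side of the threshold with library totals, 376 with RLE, 376 with DESeq2 and 374 with limma voom. The labels do not say that replicate numbers pair the samples, and no correlation passed the 0.1 set for taking them as pairs: deviations of libraries with the same number correlated from -0.0209 to 0.0923, other numbers from -0.0942 to 0.0643, and 21 of 36 combinations of a library and another group were best with the own number, against 12 by chance, a hint that they share something. A replicate block gave 4356, 8236, 14954, 15123, 5105 and 7676 genes. With it 165 of the 168 list results stayed on their side of the threshold, 2 lost their call and 1 gained it. At this depth edgeR recovered 5 of 50 genes with the smallest simulated change in the GFP-positive comparison, so small changes can be missed. Fewer genes were changed in the simulation than passed in the data, which makes the adjustment stricter there. The share missed in the data is therefore not known.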

Other observations

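Several groups of genes that no fixed list covers as a set changed with AB42, and their sets were chosen after the result was seen. Some members, such as il6, il11a and krt8, also belong to fixed lists. Genes of the IL-6 family of cytokines and receptors were among these groups. In GFP-positive cells il11a rose from 27.4 ± 1.4 to 94.1 ± 3.0 CPM (log2 fold change 1.78, edgeR adjusted p = 1.86e-16), next to clcf1 and crlf1a, and the shared receptor il6st rose from 62.5 to 99.3 CPM, while il6 itself fell from 4.1 to 1.73 CPM (edgeR adjusted p = 0.000375). In GFP-negative cells il6 rose from 2.13 to 10.1 CPM (edgeR adjusted p = 3.96e-11), il6r from 6.63 to 19.7 CPM and lifrb from 12.2 to 40.5 CPM. In both fractions il11a, crlf1a, il6st and lifrb rose. The hypothesis that the family rose as a group in GFP-positive cells did not hold by the bound set for it: the set passed (camera adjusted p = 0.000182), but 5 of 16 genes rose and 2 fell, fewer than 8. In GFP-negative cells, for which no such hypothesis was set, 11 rose and 1 fell (median 0.93, camera adjusted p = 3.98e-05).

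Of 33 epithelial genes 13 fell in GFP-positive cells and 3 rose (15 and 3 adjusted over the set alone, median -1.09, camera adjusted p = 0.00124), with epcam from 17.4 to 5.40 CPM and krt91 from 20.6 to 7.40 CPM, whereas krt8, krt18a.1 and krt4 rose. In GFP-negative cells 9 rose and 7 fell with a median of -0.015, against an upward direction of the test (camera adjusted p = 0.654). Clock genes fell in both fractions: ciarta went from 140 ± 4.3 to 23.2 ± 0.77 CPM in GFP-positive and from 174 ± 6.4 to 55.2 ± 3.4 CPM in GFP-negative cells, NR1D1 from 53.8 to 10.6 and from 44.9 to 17 CPM, while BMAL1 (ENSDARG00000006791), of the opposite phase, rose from 35.1 to 53.8 and from 22.2 to 43.9 CPM. FKBP5, a glucocorticoid-induced gene, fell from 262 ± 21 to 78.7 ± 9.0 CPM in GFP-positive and from 295 ± 8.5 to 131 ± 2.4 CPM in GFP-negative cells. Among gene families grouped by the stem of their symbols, a search over 484 tests made after seeing the data, 14 of 17 mfap genes rose in GFP-negative cells and 0 fell (median 2.07, camera adjusted p = 5.48e-09, 0.0839 with an estimated correlation).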
